A study of Cucumis sativus with 2 samples.

How the data were processed

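RNA was measured in 2 libraries from bending fruit of cucumber (Cucumis sativus) at day 2 after anthesis, 1 from the ventral side and 1 from the dorsal side of the fruit. Per the labels' protocols, total RNA was treated with DNase, poly(A) RNA was captured on oligo(dT) beads and strand-specific libraries were made after chemical fragmentation, with a size selection of the amplified cDNA. The labels name a paired-end and a single-end Illumina instrument without saying which library was read on which. TopHat2 and edgeR are listed in the submitters' processing notes, without versions. The genome build, the counting tool and whether counting used strand are not given in the sources used here.

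Both deposited tables come from 1 workbook. The first holds whole-number read counts per gene, deposited without normalization, for 20700 genes. The second holds RPKM values, which are scaled for gene length and depth, for 20815 genes, as the authors deposited them per the file headers. The 115 genes found only in the second table have an RPKM of at most 0.49. Each table pairs a cucumber gene identifier with a chromosome, a gene length, the locus of an Arabidopsis homologue (18298 genes) and a symbol or description of that homologue (8831 genes). Gene names in the text are therefore names of Arabidopsis homologues as the deposited table gives them. The tables hold no start and end positions. For all 20531 genes on the 7 numbered chromosomes, the digit after Csa in the identifier is the chromosome in the table. A spreadsheet had turned a few symbols, such as those of SEPALLATA genes, into dates; these symbols were dropped and the descriptions kept. The reference table of gene symbols at hand holds none of these identifiers and was not used.

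The ventral library held 21863715 counted reads and the dorsal library 11893394, and 451 and 1172 genes had 0 reads. The 10 most abundant genes took 4.28% of ventral and 4.98% of dorsal reads. A count of 0 allows up to 3 reads, which is 0.137 CPM in the ventral and 0.252 in the dorsal library. Reads divided by RPKM gives a length for each gene up to a constant. Among 16276 genes with an RPKM of at least 1 in both libraries, the lengths implied by the 2 libraries agreed within 1% for 88.8%, and for 99.5% of the 8625 genes with an RPKM of at least 10. The constant was set from the top of the ratio of implied to listed gene length among well-expressed genes. That the implied length does not exceed the listed gene length by more than 1% in any gene follows largely from this choice. The implied length is called exonic length here, and it could be computed for all 17462 measured genes defined below.

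With 1 library per side there are no replicates, so no test between the sides, no p-value and no standard deviation can be given, and every difference lacks a replicate check. Library scaling used the trimmed mean of M values (TMM) of edgeR 4.0.16 under R 4.3.3, which set the ventral library 2.16 times as deep as the dorsal one, against 1.84 from total reads. A gene was measured when it had at least 20 reads summed over both libraries (17462 genes). For each gene the scaled ratio of reads, ventral over dorsal, was computed with an exact conditional binomial (Clopper-Pearson) 95% interval. Intervals and floors cover counting error only, since copies made by amplification are not independent molecules and the spread between fruits is not measured. A library at 0 was set to a floor of 3 reads, and the ratio against that floor is given as at least so many fold; it leaves out the counting error of the other library, so the interval bound, which can lie closer to a ratio of 1, is given beside it. A gene is said to stand apart when its ratio is at least 2-fold either way and its interval excludes 1; this describes these 2 libraries and not the 2 sides of cucumber fruit in general.

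Before the data were examined, 33 gene lists were fixed as name patterns. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins, and lists outside percentiles 2.5 to 97.5 are said to lie outside the central range. Random lists hold unrelated genes, whereas members of a family or pathway can vary together, which 1 library per side cannot measure, so the percentiles are descriptive and are not tests. Because the patterns fitted the naming style of the deposited table poorly in places, extended lists were written after the names in the table were seen but before any read ratio was computed. The genes named in the text follow a rule fixed in advance: the first 12 genes per direction with an informative name, ranked by the interval bound nearest to a ratio of 1, and up to 3 members per direction of each list, with lists taken in order of how far their medians lie from the random lists, up to 30 genes per direction. In that ranking 3 genes higher in the ventral and 23 higher in the dorsal library carried no symbol or description and were passed over. Any gene the table calls ERF025 was also to be named, and there was none. How alike the sequences of copies with the same name are, such as the lipoxygenase, PAL2 and PP2-A1 copies, was not examined. Where copies are near-identical, reads may be shared between them, and values of single copies are uncertain.

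The alternatives fixed in advance were scaling by total reads, by DESeq2 1.42.0 size factors, by a loess centring over expression or by the deposited RPKM values, minimums of 1 and 100 reads, fold minimums of 1.5 and 4, a 99.9% interval, assumed coefficients of variation of 0.2 and 0.4 on top of counting error, and a prior count of 2. After the ratios were seen to rise with exonic length, a removal of that trend was added (lowess with a fraction of 0.3 in statsmodels 0.14.6), with random lists matched in 10 bins of expression and 10 of length. Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

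The procedure was tested on simulated counts for the 17462 measured genes, drawn with the real depths and counting error alone. Of 40 genes changed 4-fold, 40 stood apart in the right direction, as did 38 of 40 changed 3-fold and 21 of 40 changed 2-fold, while 44 of 17262 unchanged genes did. The intervals held the true ratio for 95.7% of genes. With an assumed coefficient of variation of 0.2 between samples, 536 of 17230 unchanged genes stood apart, and with 0.4, 4192 of 17233 did. With counting error alone, 4 of 100 random lists of 20 genes with no shift fell outside the central range. After a shift of 0.5 on the log2 scale 100 of 100 did. The measured ratios spread more widely: for the 20 lignin enzymes the central range ran from -0.40 to 0.60. The list check therefore does not show how small a shift the real lists could reveal.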

Results

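Poly(A) RNA of bending cucumber fruit at day 2 after anthesis was sequenced from the ventral and from the dorsal side of the fruit, with 1 library per side and no replicates. The ventral library held 21863715 reads over 20249 genes with reads and the dorsal library 11893394 reads over 19528 genes. The single comparison in this design asks which transcripts differ in level between the sides of a bending fruit. The series title points to AP2/ERF transcription factors, the family of ethylene-response and dehydration-response regulators, and to a member called CsERF025. All ratios below are ventral over dorsal after TMM scaling unless the text says higher in the dorsal library, and brackets give 95% counting intervals on the log2 scale.

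As a list, WRKY and calmodulin-like genes lay higher in the ventral library. Of 60 measured touch and wound response genes, which here are WRKY transcription factors and calmodulin-like proteins, 21 stood apart higher in the ventral library, 3 higher in the dorsal library and 36 did not stand apart. The list median was 0.77 (log2), at percentile 100 of matched random lists. WRKY53 (Csa3G119700) had 1921 ventral and 70 dorsal reads, a 12.7-fold ratio [3.32 to 4.03]. CML41 (Csa3G588520), a calmodulin-like calcium sensor, was 21.3-fold higher with 230 and 5 reads [3.17 to 6.05], and WRKY31 (Csa6G513530) was 10.7-fold higher. The exceptions were another CML41 copy (Csa3G854250), 9.29-fold higher in the dorsal library, and both WRKY13 copies (Csa2G297220 and Csa6G486880), 2.38-fold and 2.31-fold higher there. The latter WRKY13 copy had only 30 dorsal and 28 ventral reads [-2.01 to -0.42]. After removal of the trend with transcript length, described further on, the list median was 0.81, again at percentile 100, and the WRKY13 copies, at -0.98 and -0.76, were short of 2-fold and did not stand apart.

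The AP2/ERF list moved the same way. Of 39 measured members 15 stood apart higher in the ventral and 3 higher in the dorsal library, and the median of 0.61 lay at percentile 99.8. The cold- and drought-response factors DREB1D (Csa5G155570, 1343 and 37 reads), DREB1A (Csa3G180260, 583 and 21 reads) and DREB1B (Csa5G174570, 165 and 6 reads) were 16.8-fold, 12.9-fold and 12.7-fold higher in the ventral library. Lower in it were 2 RAP2.11 copies (Csa3G124760 and Csa5G146300), 4.09-fold and 4.05-fold higher in the dorsal library. These rested on few reads, 36 dorsal and 19 ventral [-2.92 to -1.19] and 15 dorsal and 8 ventral [-3.46 to -0.69]. RAP2.3 (Csa6G318160) was 2.35-fold higher in the dorsal library but short of 2-fold, at -0.89, with the length trend removed. The pattern also caught 4 genes that are not AP2/ERF factors, namely copies of the release factor ERF1-3 and of the ubiquitin ligase DRIP2. An extended list of 63 AP2/ERF genes had a median of 0.30 at percentile 93.5, within the central range, with 21 higher in the ventral and 9 in the dorsal library. With the length trend removed the fixed and extended medians were 0.76 and 0.57, against central ranges of -0.24 to 0.40 and -0.15 to 0.38. No gene of the table is named ERF025.

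Single genes with the firmest ventral excess included several of hormone metabolism and stress. GA2OX1 (Csa4G075200), a gibberellin-inactivating oxidase, had 201 ventral reads and 1 dorsal read, a 93.1-fold ratio [4.05 to 11.85]. ATACS6 (Csa4G049610), an enzyme that makes the ethylene precursor ACC, was 38.5-fold higher with 665 and 8 reads [4.28 to 6.48]. TIFY5A (Csa1G435790), a JAZ repressor of jasmonate signalling, was 29.5-fold higher with 892 and 14 reads [4.13 to 5.76]. CYP94B1 (Csa1G002090), which oxidises the active jasmonate conjugate, was 37.3-fold higher with 161 and 2 reads [3.34 to 8.28]. ICL (Csa2G420990), isocitrate lyase of the glyoxylate cycle, was 63.1-fold higher with 681 and 5 reads. MT3, a metallothionein (Csa3G105950), CHIA, an acidic chitinase (Csa5G139760), and ABR1, an AP2/ERF repressor (Csa6G486790), were 59.7-fold [4.03 to 8.95], 41.2-fold [3.49 to 8.42] and 40.5-fold [3.466 to 8.397] higher, each with 2 dorsal reads. PAT1 (Csa3G405510) and LSR3 (Csa3G121560), a late embryogenesis abundant protein, were 18.7-fold and 13.2-fold higher with 889 and 2000 ventral reads. PAL2 (Csa6G445780), 1 of several phenylalanine ammonia-lyase copies, had 111 ventral and 0 dorsal reads and was at least 17.1-fold higher against the floor of 3 reads, with a lower interval bound of 3.78 on the log2 scale.

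On the dorsal side the firmest excess was in BBX18 (Csa6G505230), a B-box zinc finger protein, with 801 dorsal and 23 ventral reads, 75.2-fold higher in the dorsal library [-6.90 to -5.64]. GA5 (Csa5G172270), a gibberellin 20-oxidase of gibberellin synthesis, was 21.3-fold higher with 809 and 82 reads [-4.76 to -4.08]. The F-box protein gene VBF (Csa1G568500) had 85 dorsal and 0 ventral reads and was at least 61.2-fold higher against the floor of 3 reads, with an interval bound of -5.61 on the log2 scale, and PRE5 (Csa1G032990), a small helix-loop-helix protein, was 59.4-fold higher with 110 and 4 reads. SLR (Csa2G200420), an Aux/IAA repressor of auxin response, was 18.2-fold higher, HSP17.4 (Csa5G197110), a small heat shock protein, 15.8-fold, and the early light-induced gene ELIP1 (Csa3G145780) 10.9-fold; UNE10 (Csa6G108570), a helix-loop-helix factor, had 168 dorsal and 26 ventral reads and a log2 ratio of -3.80. Developmental regulators in this group were the MADS-box gene AP1 (Csa6G367090), 10.1-fold higher with 122 and 26 reads, the YABBY gene YAB1 (Csa5G160210), 9.93-fold with 230 and 50 reads, and the NAC gene XND1 (Csa2G334550), 9.45-fold with 315 and 72 reads. The cytochrome P450 gene CYP78A7 (Csa2G298280) was 9.76-fold higher. All 24 of these highest-ranked genes stood apart with the length trend removed.

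**Figure D1:**
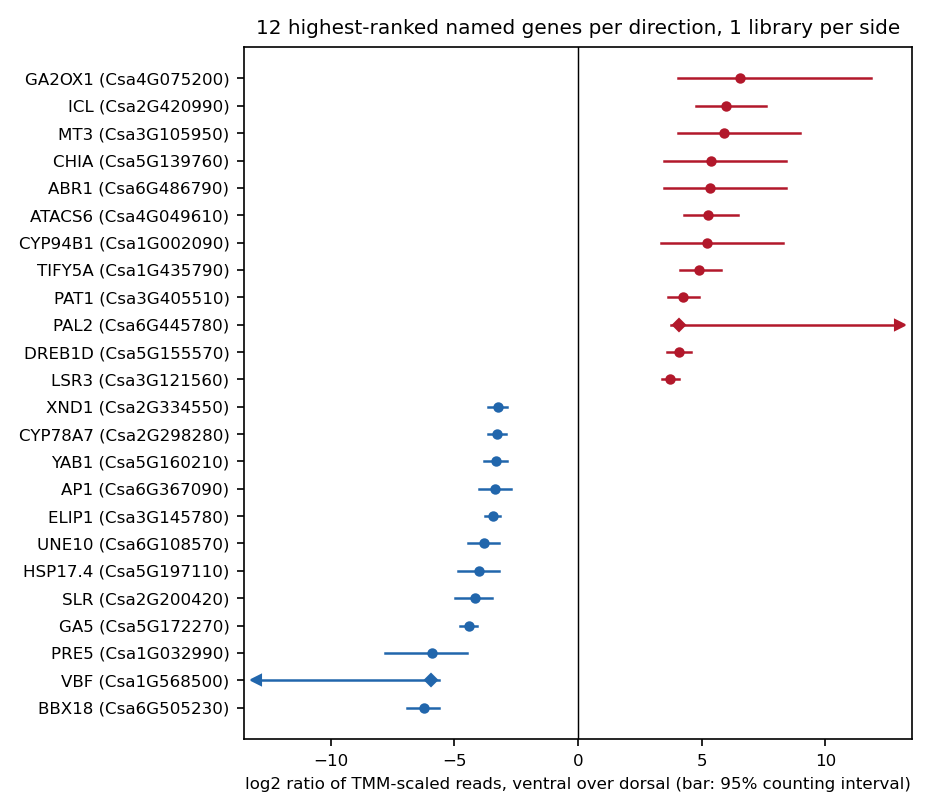
The horizontal axis is the log2 ratio of TMM-scaled reads, ventral over dorsal, for the 12 highest-ranked named genes per direction, with bars for the 95% counting interval; diamonds mark genes with 0 reads in 1 library, drawn at the floor of 3 reads, with arrowheads where the interval has no bound. Ventral-high genes (red) run from LSR3 at 3.73 to GA2OX1 at 6.54, and dorsal-high genes (blue) from XND1 at -3.24 to BBX18 at -6.23.

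Photosynthesis genes and core histones lay lower in the ventral than in the dorsal library. Of 30 photosynthesis genes, 10 stood apart higher in the dorsal library and 1 higher in the ventral library, with a median of -0.80 at percentile 0.07. Random lists matched on expression had a median of -0.34 here, so genes of like expression shared part of that value. The photosystem gene PSBW (Csa2G010330) had 30170 dorsal and 10058 ventral reads, 6.48-fold higher in the dorsal library, and LHCA2 (Csa5G589390) and PSBS (Csa7G267900) were 3.22-fold and 2.85-fold higher. The exception, PSBC (Csa2G037270), matches a chloroplast-encoded gene. Of 11 histone genes 4 stood apart higher in the dorsal library and none in the ventral library. Their median was -0.95 at percentile 1.04, beside a matched random median of -0.33. HTA12 (Csa6G303770), a histone H2A, was 3.62-fold higher in the dorsal library. Phloem markers, mostly phloem lectins, had a median of -0.55 at percentile 0.64, with 5 of 23 higher in the dorsal library, among them PP2-A1 (Csa4G500830) and PP2-A9 (Csa1G709160), 3.02-fold and 3.03-fold, and another PP2-A9 copy (Csa1G708660), 2.70-fold. The receptor kinase gene XIP1 (Csa2G372790) and another PP2-A1 copy (Csa1G703060) stood apart the other way, 4.21-fold and 6.22-fold higher in the ventral library. MADS-box genes had a median of -0.62 at percentile 0.81, with 6 of 17 higher in the dorsal and 1 in the ventral library, the latter a SEPALLATA3 homologue (Csa6G095270) with 33 and 1 reads, a log2 ratio of 3.93 with a wide interval [1.36 to 9.28]. The list also took in ULT1 (Csa7G047220), which is not a MADS-box gene and whose value is the list median with the length trend removed. Besides AP1, the dorsal-high members included a SEPALLATA1 homologue (Csa1G039900), 2.94-fold, and FUL (Csa1G039910), 2.10-fold, the latter short of 2-fold, at -0.77, with the length trend removed. With the length trend removed, the medians of these 4 lists were -0.50, -0.48, -0.20 and -0.34. Matched random lists had medians of -0.26, -0.29, -0.11 and 0.10. The 4 list medians lay at percentiles 2.84, 17.4, 27.3 and 5.23, each within the central range of lists matched on length as well. An extended list of 49 photosynthesis genes lay outside that range, at percentile 0.63.

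Among wall, cytoskeleton and other hormone lists, pectin-modifying enzymes lay higher in the ventral library, with a median of 0.74 at percentile 99.8 and 0.44 at percentile 98.6 with the length trend removed. A single member of 13, the pectin methylesterase PME5 (Csa5G162010), stood apart, 2.27-fold higher. The pattern also took in polygalacturonase and pectin methylesterase inhibitors. Brassinosteroid genes (median 0.49, percentile 98.5, 6 of 26 higher in the ventral library, among them BSL2 (Csa1G638460), 3.21-fold) and tubulin, actin and kinesin genes (median 0.35, central range -0.39 to 0.19, 6 of 49 higher and 4 lower) were outside the central range as counted but not with the length trend removed, at percentiles 91.4 and 96.1. The kinesins POK2 (Csa2G237130) and POK1 (Csa6G000650), which guide the division plane and have long transcripts, were 3.62-fold and 3.47-fold higher but fell to log2 ratios of 0.40 and 0.52 once the trend was removed; the actin ACT7 (Csa2G301530), 2.53-fold higher, still stood apart. Auxin synthesis and transport genes, mostly YUCCA oxidases, had a median of -0.78 at percentile 2.13 over 6 members, with 1 member standing apart each way, the kinase PID (Csa1G537400) being 2.05-fold higher in the ventral library; with the length trend removed the median was -0.64 at percentile 2.36, and PID moved little, from 1.04 to 0.98, but was then short of 2-fold. An extended list of 23 such genes had a median of -0.13 at percentile 21, within the central range, with 5 members higher in the ventral and 2 in the dorsal library; with the length trend removed these numbers were 0 and 4 and the median -0.24 at percentile 5.34. The brassinosteroid genes BEH4 (Csa4G083490) and BSL3 (Csa6G426880), 2.11-fold and 2.01-fold higher in the ventral library, had log2 ratios of 0.72 and 0.20 with the trend removed and did not stand apart. Among the 4 cytoskeleton genes higher in the dorsal library were MAP65-8 (Csa6G365130), MAP70-5 (Csa6G511060) and ACT11 (Csa5G182010), 2.15-fold, 2.19-fold and 2.31-fold, the last of these short of 2-fold, at -0.73, with the trend removed. ACT11 had only 31 dorsal and 29 ventral reads [-1.99 to -0.43]. In the ethylene list of 5, the transcription factor EIN3 (Csa1G601520) was 3.05-fold higher in the ventral library, and the median of 0.82 lay at percentile 96.8; with the length trend removed it was 0.87, above a central range of -0.71 to 0.61.

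The remaining lists lay within the central range as counted. Their medians were 0.30 for 47 cell cycle genes, 0.20 for 9 Aux/IAA, GH3 and SAUR genes, 0.19 for 35 jasmonate genes, 0.18 for 18 xyloglucan endotransglucosylases, 0.18 for 22 sugar genes and 0.16 for 68 genes of fruit shape families. They were -0.01 for 11 xylem markers, -0.02 for 8 TCP and growth-regulating factors, -0.02 for 20 lignin enzymes, -0.03 for 22 cellulose synthesis genes, -0.07 for 14 cytokinin genes and -0.10 for 49 epidermis and trichome markers. They were -0.13 for 52 heat shock proteins, -0.14 for 18 class III peroxidases, -0.19 for 17 expansins, -0.26 for 16 organ polarity genes, -0.29 for 10 ovule and seed markers and -0.41 for 11 auxin response factors. The peroxidase pattern took in glutathione and ascorbate peroxidases, and the epidermis pattern took in many TRICHOME BIREFRINGENCE-LIKE wall acetylation genes. With the length trend removed 6 of these lists lay outside the central range. Above it were jasmonate genes (0.40, percentile 99.7), xyloglucan endotransglucosylases (0.57, percentile 99.4) and cell cycle genes (0.26, percentile 99.1), although an extended list of 79 cell cycle genes had a median of -0.07 at percentile 21.7, with 5 members higher in the ventral and 11 in the dorsal library, and as counted a median near 0 at percentile 42.1, with 4 and 8. Below it were auxin response factors (-0.72, percentile 0.075, with 0 members higher in the ventral and 5 in the dorsal library, against 1 and 0 as counted), lignin enzymes (-0.34, percentile 1.54) and heat shock proteins (-0.21, percentile 2.37). In all, 10 of 29 lists lay outside the central range, 5 on either side, where 1.45 would be outside by chance if list members varied independently, which cannot be checked here; with the length trend removed 7 lay above and 4 below, of which 3 and 1 were in the same place before. For 4 lists with fewer than 5 measured members no percentile was computed. The gibberellin list held GA2OX1 and 2 GA2OX8 copies at log2 ratios of 6.54, 1.93 and -1.51, the ribosomal list 2 RSU2 genes at -0.21 and -1.37, the abscisic acid list ABA4 at 0.25, and the aquaporin list AQI at 0.66, which is not itself an aquaporin.

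**Figure D2:**
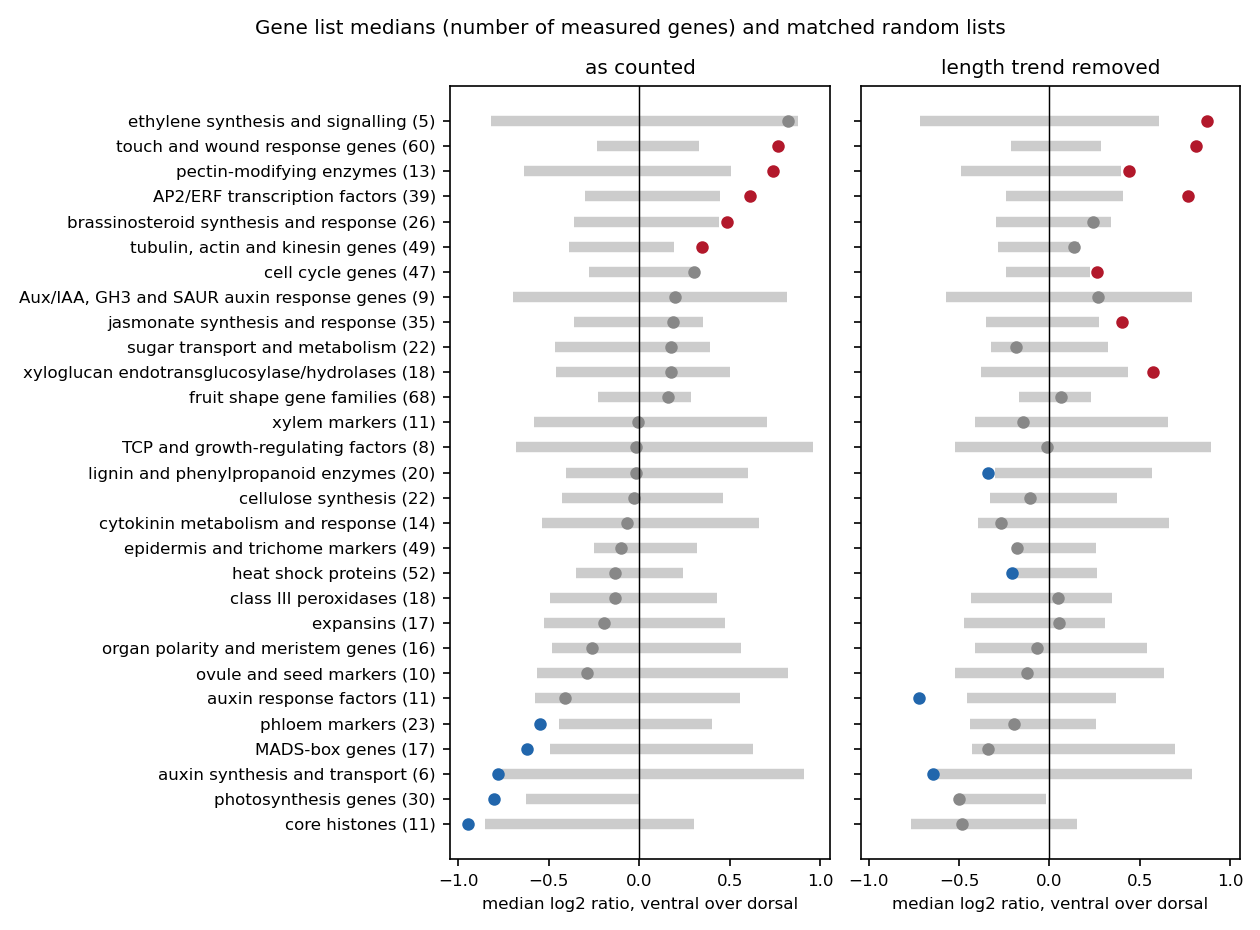
Each dot is the median log2 ratio, ventral over dorsal, of 1 gene list (number of measured genes in brackets), and each grey bar spans the central 95% of matched random list medians; red and blue dots lie above and below that range. The left panel uses the ratios as counted and the right panel the ratios after removal of the length trend; touch and wound response genes stay to the right of the grey bar in both, at 0.77 and 0.81, whereas core histones at -0.95 and -0.48 leave the range only on the left.

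Across all genes, 2304 of 17462 measured genes stood apart higher in the ventral and 2005 higher in the dorsal library. Scaling by total reads in place of TMM raises every log2 ratio by 0.23 and gives 3336 and 1283 genes, a ventral share of 72.2% in place of 53.5%; no list outside the central range changed the sign of its median. In the simulation with an assumed coefficient of variation of 0.4 between samples, 4192 of 17233 unchanged genes stood apart, close to the 4309 of 17462 observed. With 0.2 it was 536 of 17230, and which spread applies was not measured. The number of genes therefore does not by itself separate the sides from spread between samples. The ratio also rose with exonic length, with a Spearman correlation of 0.39 across 17462 genes, which are not independent replicates. The median log2 ratio went from -0.53 for exonic lengths of 607 to 856 bp to 0.74 for those above 2848 bp. Genes standing apart had a median exonic length of 1941 bp when higher in the ventral library and 940.5 bp when higher in the dorsal library, against 1464 bp for measured genes. With that trend removed, a step chosen after the trend was seen, 1911 and 1457 genes stood apart, of which 1466 and 1202 were the same genes as before.

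**Figure D3:**
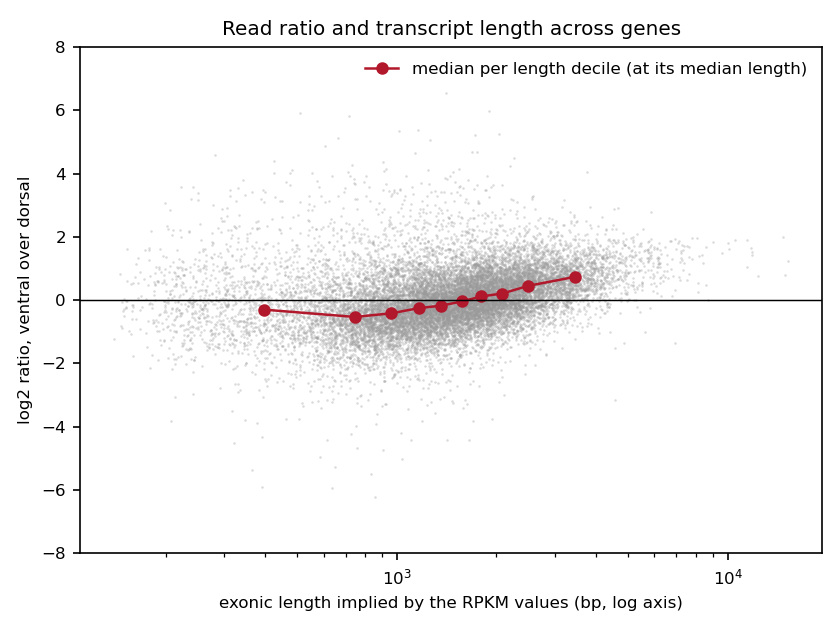
Each grey point is 1 of 17462 measured genes, with its exonic length in bp on a log axis and its log2 ratio, ventral over dorsal, on the vertical axis; red points are medians of 10 length groups drawn at their median length. The medians climb from -0.53 at a median length of 746 bp to 0.74 at 3455 bp, with the shortest group at -0.30.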

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

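The removal of the length trend was chosen after the ratios were seen, and the extended lists were added after the gene names but before the ratios were seen; the other alternatives were fixed before the data were examined. No paired analysis was possible because each side has 1 library. The number of genes standing apart (2304 higher in the ventral and 2005 higher in the dorsal library) stayed within 1.5 times with DESeq2 size factors, loess centring, minimums of 1 and 100 reads, a stricter interval, an assumed coefficient of variation of 0.2 and removal of the length trend, between 1843 and 2370 ventral-high and between 1457 and 2189 dorsal-high genes. The dorsal-high number fell to 1283 with total reads, which raise every log2 ratio by 0.23, and to 1197 with RPKM values, whose depth ratio is shifted by 0.26 on that scale while single ratios at low RPKM move either way; the ventral share was then 72.2% and 74.3%. By construction a fold minimum of 1.5 gave 4242 and 3998 genes, a fold minimum of 4 gave 480 and 277, and an assumed coefficient of variation of 0.4 gave 708 and 524. Lists outside the central range numbered 10 with the 4 scaling alternatives and the prior count, 9 with 100 reads, 10 with extended lists and 11 with the length trend removed. None of the 29 lists changed its call under the scalings or the prior count. With 100 reads the brassinosteroid list fell inside the range, at percentile 97.4, the ovule list fell outside it, at 1.97, and the auxin synthesis and transport list was left with fewer than 5 members and no percentile, which ends its call; the list of TCP and growth-regulating factors was not tested there either. With the length trend removed 6 lists lost and 7 gained a call. Those gained on the ventral side were ethylene, jasmonate, xyloglucan endotransglucosylase and cell cycle genes (the last not in its extended list, at percentile 21.7). Those gained on the dorsal side were auxin response factors, lignin enzymes and heat shock proteins. Those lost were brassinosteroid, tubulin, histone, phloem, MADS-box and photosynthesis genes (the last not in its extended list, at percentile 0.63). With extended lists the AP2/ERF and auxin synthesis lists fell inside the range, the former at 93.5, and the ethylene and cytokinin lists fell outside it. Of 60 named genes, 17 moved beyond their counting interval with total reads, 19 with RPKM values, 8 with loess centring and 24 with the length trend removed, and 0 with DESeq2 or the prior count. None of the 60 changed sign under any of these alternatives, and 10 of them, 5 per direction, no longer stood apart with the length trend removed. Other scalings also took named genes below 2-fold. With total reads these included MAP65-8 at -0.87, MAP70-5 at -0.90 and FUL at -0.84. With loess centring they included LHCA2 at -0.97, BSL3 at 0.96 and PID at 0.98. Depth limits genes near 20 reads, whose intervals span several fold.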

Other observations

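The genes of this part were chosen after their values were seen, from the extended lists or the table of all genes, except where they are named above; the test on core histones alone, and the use of the extended list in the test on photosynthesis genes, were also chosen after their results were seen.

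Gibberellin genes stood apart in both directions. Of 24 measured genes in the extended list, 8 stood apart higher in the dorsal and 6 higher in the ventral library, and the median of -0.26 lay at percentile 9.77, within the central range. Enzymes of gibberellin synthesis were among the dorsal-high genes, with GA5 (Csa5G172270) 21.3-fold, KAO2 (Csa3G903530) 6.22-fold with 2691 and 935 reads, and KAO1 (Csa6G079220) 3.30-fold with 3254 and 2132 reads. The inactivating GA2OX1 (Csa4G075200) was 93.1-fold and a GA2OX8 copy (Csa1G064730) 3.82-fold higher in the ventral library, where the DELLA repressor genes RGA1 (Csa5G421370 and Csa5G569350) were 4.78-fold and 3.19-fold and the receptor gene GID1B (Csa7G391240) 5.30-fold higher. No division by function was tested, and a second GA2OX8 copy (Csa5G052540) had a log2 ratio of -1.51 and 1 KAO1 copy (Csa3G127130), with 65 ventral and 15 dorsal reads, was 2.01-fold higher in the ventral library, at the 2-fold limit.

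Other hormone genes outside the fixed patterns also differed. In the extended ethylene list of 13 genes, 5 stood apart higher in the ventral library and none in the dorsal library, with a median of 0.73 at percentile 99.4; the receptor gene ETR2 (Csa3G141850) was 6.14-fold higher with 2362 and 178 reads. With the length trend removed the median was 0.65, above the central range of -0.41 to 0.39. In the extended cytokinin list of 41 genes, 13 stood apart higher in the dorsal and 8 in the ventral library, with a median of -0.32 at percentile 1.72, and -0.23 at percentile 3.72 with the length trend removed. The response regulator genes RR17 (Csa5G223020) and ATRR4 (Csa3G822100) were 7.38-fold and 3.33-fold higher in the dorsal library. In the extended pectin list of 27 genes, 8 stood apart higher in the ventral library, most of them galacturonosyltransferases of pectin synthesis such as GAUT14 (Csa3G516510) at a log2 ratio of 1.85. The extended lists of 28 aquaporins and 51 ribosomal protein genes had medians of -0.20 and -0.41, at percentiles 19.6 and 20.8.

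The second-ranked ventral-high gene of all was Csa3G042390, which carries no symbol or description in the table. It had 725 ventral and 6 dorsal reads, a 56.0-fold ratio with a counting interval from 4.68 to 7.26 on the log2 scale. Its listed Arabidopsis homologue, AT5G52020, is known in Arabidopsis as an AP2/ERF gene, although the table does not say so. Nor does the table say whether this gene is the CsERF025 of the series title.

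The ventral excess of the touch and wound list was weighed against the length trend and against collection at different times of day. Heat shock proteins did not share that excess. Of 52 such genes, 10 stood apart higher in the dorsal and 5 in the ventral library, beside 2005 and 2304 of all 17462 measured genes. Their median of -0.13 lay within the central range as counted. The touch and wound list median stayed at percentile 100 of random lists matched on expression and length once the trend was removed, which argues against the trend as its whole cause. For time of day, 11 genes with symbols of dawn-phased and 13 with symbols of dusk-phased clock genes had medians of 0.47 and 0.70 with the length trend removed. The difference was -0.23 with a bootstrap 95% interval over genes from -1.03 to 0.73. The bound set before the result was seen covered the difference alone, which fell short of it. The interval was not part of that bound. It reached past the bound in both directions and is too wide to decide. The bootstrap took genes as independent, although several share the symbol GI or CDF3. The genes called CDF1 list different Arabidopsis loci, AT5G23040 and AT5G62430, so not every member need be a clock gene. As counted, 3 dawn genes stood apart higher in the ventral library, such as RVE1 (Csa5G341040) at 4.01-fold, and 2 higher in the dorsal library, such as LHY1 (Csa6G095910) at 4.09-fold, whereas 6 dusk genes stood apart higher in the ventral library, 4 of them GI copies, and none in the dorsal library. The hour of collection stays open, and if it differed it cannot be told apart from the side. The side of the fruit, the fruit sampled, handling and wounding before extraction were not tested. With 1 library per side, any of these that differed between the libraries would coincide with the side.

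The dorsal excess of photosynthesis genes and core histones was weighed against the length trend, since both groups have short transcripts. For core histones the trend is a candidate explanation, as their median moved from -0.95 to -0.48 and to percentile 17.4 once it was removed, and to percentile 19.2 in the extended list. Photosynthesis genes moved to percentile 2.84 in the fixed list, just inside the central range, and to 0.63 in the extended list of 49 genes, outside it, so for them the trend cannot be told apart from a difference of the sides. The bound set before the result was seen covered the fixed list alone, and its percentile fell on the side set for the trend as cause. A value just inside the range does not show that the trend is sufficient. The fixed list median less the matched random median was -0.46 as counted and -0.24 with the trend removed. The extended list was brought in afterwards. The side of the fruit stays an untested explanation for both groups.

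The length trend itself was weighed against 2 explanations. The rank correlation weights all genes equally, so a few abundant genes could hardly produce it whatever the data. It was above 0.2 in 18 of 20 bins of mean expression, from 0.09 and 0.15 in the 2 lowest bins to 0.56 in the highest. The trend did not rest on the gene groups above. The rank correlation was 0.34 across the 12638 genes that neither stood apart nor belonged to any of the 33 lists. A difference in RNA integrity, fragment size or read layout between the libraries may produce such a trend, as may a difference of the sides in which long transcripts are made; neither can be tested from counts per gene.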
